A study of Lemna aequinoctialis with 6 samples.

How the data were processed

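The data are poly-A selected RNA-seq libraries of *Lemna aequinoctialis*, sequenced as 150-bp read pairs per the labels' protocols, with 3 control libraries and 3 libraries of cultures given indole-3-lactic acid (ILA). The authors deposited a table of estimated counts per gene, which need not be whole numbers, and a table of FPKM values, scaled by the authors for gene length and library size. Per the submitters' processing notes, RSEM 1.3.3 and DESeq2 1.42.0 were used. The assembly, the aligner and the details of the FPKM calculation are not given in the sources used here. The 6 deposited copies of each table were identical, and 1 copy of each was used. Between 6.55% and 7.38% of the gene values per library were not whole numbers, compared as deposited with no tolerance. The authors' deposited comparison table gives log2 fold changes, p-values and adjusted p-values for 408 genes. Its group signal values, headed as read counts per the file headers, equal the authors' counts after DESeq2 size-factor scaling, averaged over the 3 libraries, in 408 of 408 genes within a relative tolerance of 1e-06.

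The gene IDs carry no coordinates, and no genome was used here. Genes are named by the annotation text in the deposited tables, the Swiss-Prot hit first, then the KO text, then the NR text. An informative name was found for 29.4% of the 66810 IDs. A name is that of the best hit in another species, and several IDs can carry one name. Reads of such IDs may be divided between them, so their levels are uncertain.

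Counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr by group and the quasi-likelihood test, without covariates. This left 31497 IDs holding 99.48% of counts. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed the threshold. The standard error of a log2 fold change was derived as its size divided by the square root of the F statistic. CPM values are counts relative to the TMM-adjusted library sizes, given as mean ± SD over 3 libraries. The libraries held 19056410 to 23722169 counts each, and genes with few counts are given with an interval that covers counting error only.

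The groups, the tests, most alternatives, the rule for named genes and 33 gene lists were fixed before the data were examined. The lists were matched on the annotation text and tested with camera (limma 3.58.1, preset correlation 0.01), again with the correlation estimated from the data, and with fry. Lists with under 5 measured members were counted and not tested. After the annotation text had been seen, and before any test was run, 3 patterns that matched inside other words were corrected, in the detoxification, bacterial and animal lists. The rule for named genes took the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM in the higher group, an informative name and all ILA libraries on one side of all controls, with one ID per name. It also took from each list up to 4 members with the smallest adjusted p, or, where none passed, the 2 with the highest level. Finally, it took the 3 largest rises and falls with a name from the authors' deposited table. Not every gene the rule selects is named in the text.

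The alternatives were DESeq2 size factors, DESeq2 1.42.0 with its own test, no low-count filter, a filter of 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM values, an FPKM filter, a block for the replicate number and each library left out. Alternatives added after the data had been seen were counts summed per Swiss-Prot hit, IDs with a Swiss-Prot hit only, the lists as first written, DESeq2 without independent filtering, camera on log2(FPKM + 1), and the FPKM alternatives for results they had not been planned for.

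The scripts were tested on simulated data with 200 genes changed among counts drawn from the means and library sizes of these libraries. For the comparison of ILA with control, edgeR called 18.2% of genes changed 1.5-fold, 57.1% of those changed 2-fold and 95.2% of those changed 4-fold. The changed genes were drawn at all levels of expression and were fewer than the 2145 called in the data. These shares therefore need not hold for the data. The share of false calls depended on how the spread was simulated. With dispersions on the fitted trend it averaged 5.1% over 10 simulations (0.9% to 10.4%). With per-gene dispersions it averaged 10.6% (5% to 13.4%), above the nominal 5%. A first simulation had used per-gene dispersions, and the trend was adopted after its result had been seen, so both are given. The simulated genes were independent, so the camera test was not checked against correlated genes.

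The extra lists, the random lists matched on expression and the enrichment of annotated processes, reported as additional observations, were added after the fixed lists had been tested. For 2 of these tests, those of matched random lists and of senescence for light harvesting genes, the criteria were written before the values they measure had been seen. The median of the light harvesting list was known by then from the test of the fixed lists. For summed phosphate genes, a first criterion compared shares before and after summing, but the share of rises also went from 3.2% to 7.9% over all genes, so it was replaced after its value had been seen by a comparison with random lists of sums. Replication fork proteins were taken out of the clock list, pyrophosphatases out of the lipid exchange list, and a cinnamyl alcohol dehydrogenase and a heat shock protein out of the low oxygen list, after their values had been seen. The pattern for cytosolic ribosomal proteins was corrected after a first result, because it had also matched plastid and mitochondrial proteins. The tests of the lipid exchange and low oxygen lists were narrowed, after results for the whole lists had been seen, to members whose values had not been seen when the lists were drawn up, of which the corrected lipid exchange list has none. For these lists and for the ribosomal proteins the criteria were changed after results had been seen. To reject a fall of plastid ribosomes alone, a call of the cytosolic list with an estimated correlation was then also asked for, because random lists do not allow for correlation between members, and this turned the verdict from rejected to open. Python 3.11.15, scipy 1.17.1 and pandas 2.3.3 were used for these steps.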

Results

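Messenger RNA was sequenced from cultures of the duckweed *Lemna aequinoctialis*, a small floating flowering plant, grown with or without indole-3-lactic acid (ILA). ILA is an indole compound derived from tryptophan and is related in structure to the auxin indole-3-acetic acid. There were 3 control libraries and 3 ILA libraries, from cultures grown for 28 days at 25 °C with 16 h of light and 8 h of darkness. The labels give no dose, and the column names of the deposited tables give 100 µM. Estimated counts summed to 20588332, 22627106 and 23722169 in control replicates 1 to 3 and to 19056410, 22861493 and 21926552 in ILA replicates 1 to 3, over 66810 gene IDs. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The first principal component, with 57.6% of the variance, placed the controls between -21.07 and -12.65 and the ILA libraries between 11.62 and 22.13.

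The comparison of ILA with control asked how added ILA changes the transcriptome of this plant. Many genes of light harvesting and carbon fixation fell with ILA, 70 of 100 measured light harvesting and photosystem genes among them. Some genes of phosphate supply, such as purple acid phosphatases, and phenylalanine ammonia-lyase genes were among those that rose. IAA16, an auxin-responsive repressor, rose from 74.0 ± 2.73 to 139 ± 20.3 CPM (library-scaled counts; mean ± SD, n = 3 per group). Of 31497 gene IDs tested, 2145 passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1020 of them higher and 1125 lower with ILA. Among these called genes the falls were smaller, with a median log2 fold change of -0.53 against 0.79 for the rises. The called falls were also in more abundant genes (median 49.8 against 23.2 CPM), where smaller changes can pass the threshold. Among the 510 genes that also changed at least 2-fold, 381 were higher and 129 lower, with median levels of only 3.01 and 2.77 CPM. The 129 became 69 without control replicate 1, 214 without a low-count filter, 48 on log2(FPKM + 1), 45 with the FPKM filter and 20 with counts summed per Swiss-Prot hit, and the 381 became 215 and 107 in the last 2. Leaving out control replicate 1 gave 1039 genes (543 higher, 496 lower, 326 at least 2-fold), leaving out ILA replicate 1 gave 1060 (549 higher, 511 lower), and leaving out ILA replicate 2 gave 723 lower genes. On the log2(FPKM + 1) scale, to which TMM scaling was not applied, 64.7% of the 1212 genes called were higher, against 47.6% in the count test.

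Among genes with an informative annotation and at least 5 CPM in the higher group, the largest rises included genes of phosphate release. The gene annotated as inorganic pyrophosphatase 1 (Cluster-4469.34627) rose from 0.433 ± 0.0615 to 11.4 ± 6.33 CPM, a log2 fold change of 4.71 ± 0.42 (SE; adjusted p = 5.2e-05). One ID annotated as inorganic pyrophosphatase 2 (Cluster-4469.34624) rose by 4.51 ± 0.34. In each named gene past the threshold the 3 ILA libraries lay on one side of the 3 controls. Several IDs carry the pyrophosphatase annotations and may share reads, so the level of each is uncertain. Phospholipase A(1) LCAT3 (Cluster-6586.0), which cleaves phospholipids, rose from 1.54 ± 0.396 to 17.9 ± 7.05 CPM, and purple acid phosphatase 10 (Cluster-4469.45983), a secreted phosphatase, from 1.21 ± 0.257 to 11.5 ± 3.52 CPM. NDR1/HIN1-like protein 10, peroxidase 4, post-GPI attachment to proteins factor 3, U-box domain-containing protein 35, organic cation/carnitine transporter 3 and a glutathione S-transferase completed the 10 largest rises at that level, with log2 fold changes from 2.25 to 3.74. The largest fall at that level was in an alpha carbonic anhydrase 1 (Cluster-4469.33966), an enzyme that interconverts carbon dioxide and bicarbonate, from 16.8 ± 4.91 to 2.32 ± 0.603 CPM (log2 fold change -2.86 ± 0.24, adjusted p = 3.22e-05). The other 9 largest falls at that level lay between -1.85 and -1.27, and larger changes at lower levels are given with the authors' table below. They were a proline-rich protein (Cluster-4469.2519), the proline-rich protein DC2.15, a putative lipid-binding protein, serine incorporator 3, lipid transfer protein EARLI 1, glutamate receptor 2.7, a putative glutaredoxin-C2, transcription factor ILI6 and a RuBisCO small subunit.

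Most light harvesting and photosystem genes fell. Of 100 measured members of that list, 70 fell, none rose and 30 did not pass the threshold, with a median log2 fold change of -0.56 (75 fell when adjusted over the list alone). By limma on the log2(FPKM + 1) scale 42 fell, 31 did with the FPKM filter, and 55 to 70 did with a library left out. Photosystem I chlorophyll a/b-binding protein 3-1 (Cluster-4469.27813), an antenna protein, went from 1310 ± 57.2 to 802 ± 46.0 CPM, a log2 fold change of -0.71 ± 0.08 (SE; adjusted p = 0.000356). The antenna protein CP24 10A and the photosystem I reaction center subunit V each had a log2 fold change of -0.73 ± 0.09. Of 45 Calvin cycle and photorespiration genes, 23 fell and 1 rose (26 and 1 when adjusted over the list alone), with 20 to 23 falls when a library was left out, 16 on the log2(FPKM + 1) scale and 9 with the FPKM filter. RuBisCO activase (Cluster-4469.27157), which keeps the carbon-fixing enzyme RuBisCO active, went from 8350 ± 930 to 4800 ± 261 CPM, and glycolate oxidase 2 from 661 ± 47.4 to 378 ± 45.2 CPM. Of 65 chlorophyll and carotenoid synthesis genes, 28 fell and 1 rose (34 and 2 when adjusted over the list alone), among them magnesium protoporphyrin IX methyltransferase, at -0.79 ± 0.10. The falls in this list numbered 12 without control replicate 1, 18 without control replicate 3, 10 without ILA replicate 1 and 17 without ILA replicate 2, 11 on the log2(FPKM + 1) scale and 8 with the FPKM filter. The 3 lists were lower as sets by camera with a preset correlation (adjusted p = 2.12e-42, 4.18e-16 and 4.93e-14), and none was called with an estimated correlation (adjusted p = 0.383 for each). Fry, which does not compare a list with other genes, called all 3 lower (adjusted p = 0.0317, 0.0449 and 0.042).

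**Figure D1:**
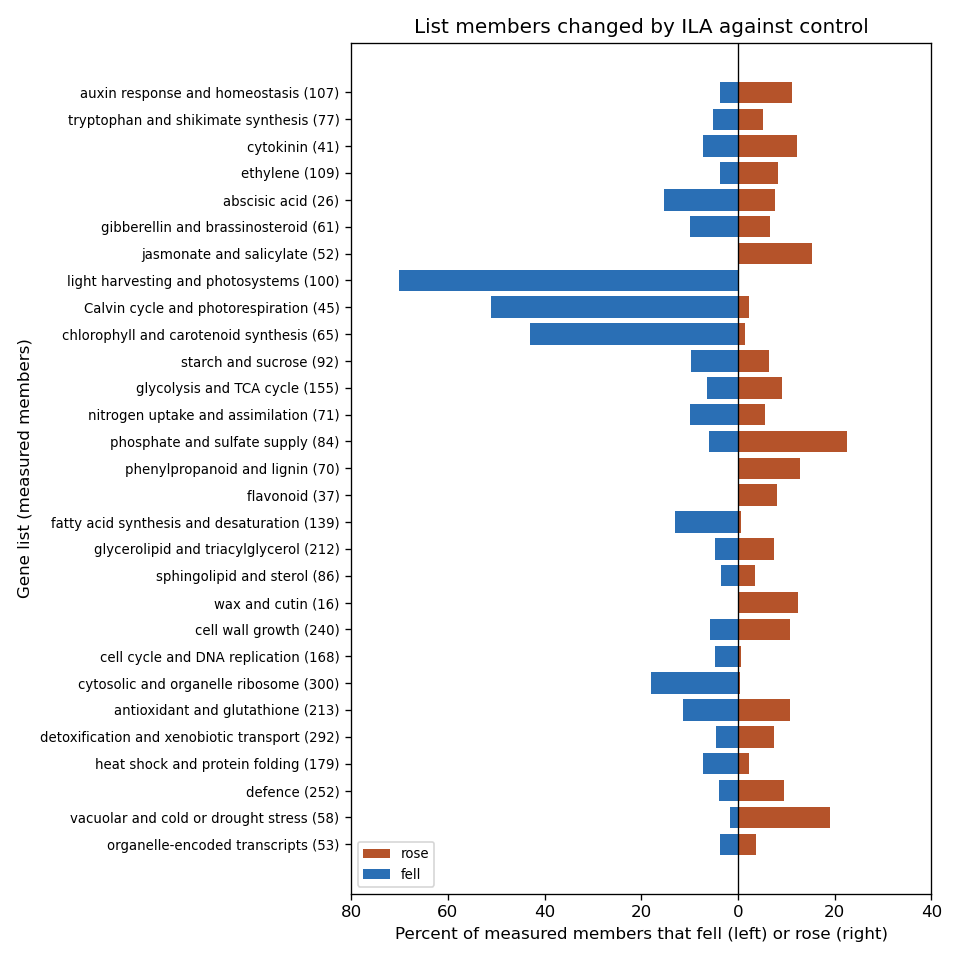
Percent of the measured members of each gene list that fell (bars to the left) or rose (bars to the right) with ILA, by the edgeR test over 3 control and 3 ILA libraries; the number of measured members follows each list's name. The light harvesting list has the longest bar, with 70 of 100 members lower and 0 higher.

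Some ribosomal protein genes fell. Of 300 measured members of the cytosolic and organelle ribosome list, 54 fell and 1 rose, with a median of -0.32, and 146 fell when adjusted over the list alone. The share past the threshold, 18.3%, was near the 16.0% of the median random list matched on expression (percentile 86.14). That comparison was added after the fixed lists had been tested. The 4 members with the smallest adjusted p were all plastid ribosomal proteins, such as uL11c (115 ± 0.875 against 69.9 ± 6.12 CPM) and cS23 (40.1 ± 2.31 against 24.5 ± 1.94 CPM). The falls numbered 32 without ILA replicate 1, 112 without control replicate 3 and 108 without ILA replicate 3. They numbered 117 with DESeq2's test, 129 without a low-count filter, 32 on the log2(FPKM + 1) scale and 26 with the FPKM filter. Of 139 fatty acid synthesis and desaturation genes, 18 fell and 1 rose (21 and 3 when adjusted over the list alone), among them 3-ketoacyl-CoA synthase 10, an enzyme of very-long-chain fatty acid elongation, at -0.44 ± 0.08. The falls in this list numbered 3 without control replicate 1 or without ILA replicate 1, 7 without ILA replicate 2 and 11 without control replicate 3, and 2 on the log2(FPKM + 1) scale with or without the FPKM filter. In the heat shock and protein folding list 13 of 179 members fell and 4 rose (14 and 5 when adjusted over the list alone), and the members named by the rule included the plastid chaperonins RuBisCO large subunit-binding protein alpha, at -0.58 ± 0.10, and chaperonin 60 beta 2, at -0.54 ± 0.10. Without control replicate 1 or ILA replicate 1, and on the log2(FPKM + 1) scale, 7 of its members fell, and 6 with the FPKM filter. In the cell cycle and DNA replication list 8 of 168 members fell and 1 rose, and 21 fell when adjusted over the list alone. Of all 31497 tested IDs, 1125 fell and 1020 rose. For the cell cycle list, the counts below are of its members. The falls numbered 2, 1 and 14 without control replicate 1, 2 or 3, and 2, 1 and 15 without ILA replicate 1, 2 or 3. They numbered 18 with DESeq2's test, 21 without a low-count filter, and 0 by limma on the log2(FPKM + 1) scale, where 22 were lower at an unadjusted p under 0.05. Camera with a preset correlation called these 4 lists lower (adjusted p = 2.65e-23, 0.00336, 0.00908 and 0.000911). With an estimated correlation none was called (adjusted p = 0.524, 0.383, 0.738 and 0.738). Fry called only the fatty acid list (adjusted p = 0.0317), and not those of the ribosome (0.167), heat shock (0.426) or the cell cycle (0.439). The heat shock list was not called without ILA replicate 2 (adjusted p = 0.0912), nor the cell cycle list without control replicate 2 (adjusted p = 0.116).

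Some phosphate supply genes rose. Of 84 measured members of the phosphate and sulfate supply list, 19 rose, 5 fell and 60 did not pass the threshold, with a median of 0.07 (21 rose and 8 fell when adjusted over the list alone). Glycerophosphodiester phosphodiesterase GDPD3 (Cluster-4469.40409), which breaks down products of phospholipid cleavage, rose from 52.6 ± 3.45 to 144 ± 15.4 CPM, a log2 fold change of 1.45 ± 0.10 (SE; adjusted p = 5.75e-06). SPX domain-containing protein 2 (Cluster-4469.6361), of a family of phosphate sensors, rose from 33.0 ± 2.33 to 114 ± 30.1 CPM. Purple acid phosphatase 3 rose from 22.1 ± 0.876 to 76.7 ± 19.2 CPM. The list was higher as a set by camera (adjusted p = 0.00336 with a preset correlation), and was not called with an estimated correlation (adjusted p = 0.383). Fry called it higher (adjusted p = 0.0317). The falls numbered 1 without control replicate 1 or on the log2(FPKM + 1) scale, and 2 without ILA replicate 1. With the FPKM filter 12 rose and 0 fell. The vacuolar and cold or drought stress list was also higher, with 11 of 58 members up and 1 down, or 15 and 2 when adjusted over the list alone (adjusted p = 0.00336, and adjusted p = 0.471 with an estimated correlation). It was not called by camera once counts were summed per Swiss-Prot hit (adjusted p = 0.0845), nor by fry (adjusted p = 0.153). Its named members were aquaporins, channels for water and small solutes. TIP4-4 rose by 0.59 ± 0.10 and NIP5-1 by 0.65 ± 0.11, while TIP2-1 was at -0.50 ± 0.09. Without control replicate 1, 4 members of this list rose, 6 did without control replicate 3 or ILA replicate 2, 7 did on the log2(FPKM + 1) scale and 3 with the FPKM filter.

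**Figure D2:**
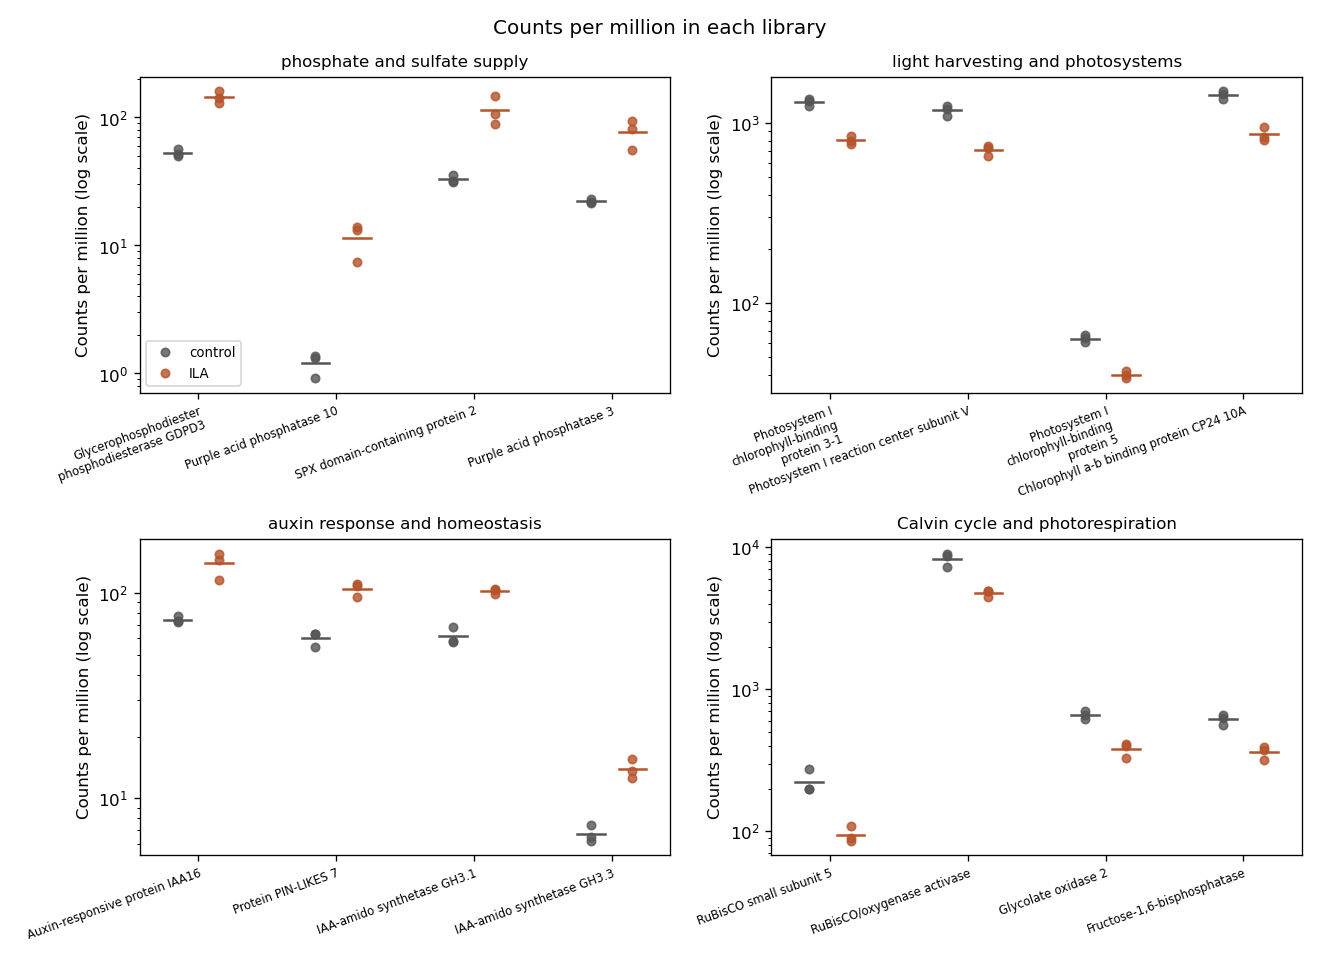
CPM on a log axis for the 4 genes named from each of 4 lists, with 1 point per library, 3 control (grey) and 3 ILA (orange), and a line at each group's mean. In each of the 16 genes the 3 ILA libraries lie on one side of the 3 controls.

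Auxin genes changed in part. Of 107 measured members, 12 rose and 4 fell (16 and 5 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.513). The auxin-responsive repressor IAA16 (Cluster-4469.27410) rose from 74.0 ± 2.73 to 139 ± 20.3 CPM. GH3.1 and GH3.3, which join indole-3-acetic acid to amino acids, rose by 0.73 ± 0.09 and 1.04 ± 0.14, and PIN-LIKES 7 by 0.79 ± 0.09. With a library left out the rises numbered 7 to 11 and the falls 1 to 4, and they numbered 9 and 2 on the log2(FPKM + 1) scale and 7 and 0 with the FPKM filter. In the cytokinin list 5 of 41 members rose and 3 fell, and adenylate isopentenyltransferase 5, which makes cytokinins, went from 67.7 ± 7.66 to 28.9 ± 1.58 CPM. In the gibberellin and brassinosteroid list 4 of 61 rose and 6 fell, with gibberellin 20 oxidase 1-B at -1.01 ± 0.15. In the ethylene list 9 of 109 rose and 4 fell, and an aminocyclopropanecarboxylate oxidase went from 242 ± 9.94 to 153 ± 9.50 CPM. In the abscisic acid list 2 of 26 rose and 4 fell, and in the jasmonate and salicylate list 8 of 52 rose and none fell in edgeR or DESeq2, while 5 were lower at an unadjusted p under 0.05 in edgeR. None of these 5 lists was called by camera, the lowest adjusted p being 0.163, for jasmonate and salicylate, which was called once counts were summed per Swiss-Prot hit (adjusted p = 0.0118, against 0.566 per ID with an estimated correlation). When adjusted over the list alone, 5 rose and 5 fell for cytokinin, 4 and 6 for gibberellin, 11 and 5 for ethylene, 6 and 5 for abscisic acid, and 10 and 0 for jasmonate. Their counts moved with single libraries. With a library left out the rises numbered 2 to 4 for cytokinin, 2 to 6 for gibberellin, 4 to 11 for ethylene, 0 to 5 for abscisic acid and 3 to 6 for jasmonate, and the falls 1 to 3, 2 to 6, 1 to 4, 1 to 4 and 0 to 1. The abscisic acid list had 5 members up and 2 down without ILA replicate 3, the other way from the full set, and 0 up and 1 down without control replicate 1 or ILA replicate 1. On the log2(FPKM + 1) scale the rises and falls of the 5 lists numbered 3 and 1, 1 and 2, 7 and 2, 0 and 1, and 6 and 0, and with the FPKM filter 1 and 1, 0 and 1, 2 and 2, 0 and 0, and 2 and 0. The tryptophan and shikimate list had 4 members up and 4 down of 77 (5 and 8 when adjusted over the list alone), with 2 to 7 up and 1 to 6 down when a library was left out, 4 and 1 on the log2(FPKM + 1) scale and 3 and 0 with the FPKM filter. Both IDs named as phospho-2-dehydro-3-deoxyheptonate aldolase, the entry enzyme of the shikimate pathway, rose (0.91 ± 0.11 and 0.94 ± 0.13).

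Genes of carbon use and of cell walls changed in both directions, and phenylpropanoid genes past the threshold rose. Beta-amylase (Cluster-4469.22571), which releases maltose from starch, rose from 42.9 ± 2.24 to 149 ± 27.2 CPM, and starch synthase 4 went from 26.8 ± 1.66 to 13.7 ± 3.49 CPM, in a starch and sucrose list with 6 members up and 9 down of 92. In the glycolysis and TCA cycle list 14 of 155 rose and 10 fell, and on the log2(FPKM + 1) scale camera called it higher (adjusted p = 0.0447, against 0.349 in the count test and 0.832 there with an estimated correlation). Phosphofructokinases 7 and 3 rose, by 0.77 ± 0.10 and 0.61 ± 0.09, and the plastid phosphoglycerate kinase was at -0.69 ± 0.10. In the phenylpropanoid and lignin list 9 of 70 rose and none fell (camera adjusted p = 0.0833), while 6 were lower at an unadjusted p under 0.05 in edgeR and 1 fell with DESeq2's test. The named members were phenylalanine ammonia-lyases, the entry enzymes of the pathway, one of which (Cluster-4469.24541) rose from 545 ± 61.9 to 1400 ± 566 CPM. Several IDs carry this annotation, so the level of each is uncertain, and 17 members rose without ILA replicate 2. Camera called the list higher without that library (adjusted p = 3.02e-05), without control replicate 1 (adjusted p = 0.0167), without a low-count filter (adjusted p = 0.0166, with 14 members up) and with counts summed per Swiss-Prot hit (adjusted p = 0.0359). With an estimated correlation or by fry it was not called (adjusted p = 0.738 and 0.54). Probable pectinesterase 15 (Cluster-4469.31472), which modifies cell wall pectin, rose from 27.4 ± 3.43 to 119 ± 20.4 CPM (log2 fold change 2.12 ± 0.13, adjusted p = 3.46e-06), in a cell wall list with 26 members up and 14 down of 240. Endoglucanase 6 was at -0.91 ± 0.12. In the nitrogen list 4 of 71 rose and 7 fell. Asparagine synthetase rose from 93.4 ± 20.5 to 236 ± 73.7 CPM, and the plastid glutamine synthetase leaf isozyme went from 1830 ± 119 to 1120 ± 124 CPM. When adjusted over the list alone, the rises and falls numbered 6 and 10 for starch, 17 and 16 for glycolysis, 9 and 3 for phenylpropanoids, 32 and 20 for the cell wall and 5 and 8 for nitrogen. With a library left out the rises numbered 4 to 6 for starch, 6 to 15 for glycolysis, 8 to 17 for phenylpropanoids, 11 to 21 for the cell wall and 1 to 4 for nitrogen, and the falls 1 to 8, 5 to 14, 0 to 1, 7 to 15 and 6 to 7. On the log2(FPKM + 1) scale the rises and falls of these lists numbered 5 and 3, 14 and 3, 9 and 0, 16 and 5, and 1 and 4, and with the FPKM filter 2 and 1, 6 and 2, 1 and 0, 9 and 3, and 0 and 3.

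Of 213 antioxidant and glutathione genes 23 rose and 24 fell, and the 1-Cys peroxiredoxin PER1 rose from 165 ± 7.49 to 345 ± 18.6 CPM. Of 252 defence genes 24 rose and 10 fell, and pathogenesis-related protein 1A rose from 137 ± 8.89 to 289 ± 42.3 CPM. Of 292 detoxification and transport genes 22 rose and 13 fell, with DETOXIFICATION 21 up by 0.70 ± 0.09. Of 212 glycerolipid and triacylglycerol genes 16 rose and 10 fell, and monogalactosyldiacylglycerol synthase 3, which makes galactolipids, rose from 3.09 ± 0.827 to 11.7 ± 4.88 CPM. The flavonoid list had 3 members up and 0 down of 37, the sphingolipid and sterol list 3 up and 3 down of 86, and the wax and cutin list 2 up and 0 down of 16. When adjusted over the list alone, the rises and falls numbered 29 and 41 for antioxidant, 24 and 15 for defence, 28 and 17 for detoxification and 19 and 14 for glycerolipid genes, and were as above for the last 3 lists. Camera called none of these 7 lists, nor those of starch, glycolysis, the cell wall, nitrogen and tryptophan. With a library left out the rises numbered 14 to 20 for antioxidant, 11 to 26 for defence, 10 to 20 for detoxification, 10 to 16 for glycerolipid, 0 to 2 for flavonoid and 0 to 3 for sphingolipid genes, and the falls 13 to 28, 6 to 16, 3 to 14, 5 to 11, 0 to 1 and 1 to 5, while the wax list stayed at 2 and 0. On the log2(FPKM + 1) scale the rises and falls of the 7 lists numbered 14 and 12, 16 and 3, 13 and 2, 10 and 4, 1 and 0, 1 and 0, and 2 and 0, and with the FPKM filter 9 and 8, 13 and 2, 10 and 1, 3 and 1, 0 and 0, 0 and 0, and 1 and 0. The median and the mean log2 fold change differed in sign for the auxin, ethylene, wax and cutin, antioxidant and detoxification lists (-0.01 and 0.05 for auxin). For the antioxidant and starch lists camera's direction was down while the mean was above 0 (0.05 and 0.04).

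Control replicate 1 stood apart in several library measures. Gene IDs picked by annotation text to reflect ribosomal DNA, such as protein TAR1, ribosomal RNA gene or senescence-associated protein, took 0.967% of its counts. In the other 5 libraries they took 0.287% to 0.456%. The organelle-encoded list took 0.08%, against 0.046% to 0.054%. Of 53 measured organelle-encoded list members 2 rose and 2 fell (2 and 2 when adjusted over the list alone), with 0 to 2 up and 2 to 5 down when a library was left out. The list was not called by camera (adjusted p = 0.0845), but was called lower without control replicate 2 (adjusted p = 0.00619), without ILA replicate 1 (adjusted p = 0.0261), on log2(FPKM + 1) (adjusted p = 0.0306) and on log2(FPKM + 0.1) (adjusted p = 0.042), and not with an estimated correlation (adjusted p = 0.738). The 10 most abundant genes of each library took 6.25% ± 0.284 of counts in controls and 5.09% ± 0.193 with ILA (SD, n = 3). The lists for other organisms were small. The animal list had no member in the table, the fungal list 1 measured member with 0 past the threshold, and the bacterial list 9 with 0 past it in edgeR or DESeq2, 2 of which were lower at an unadjusted p under 0.05 in both. The members of the bacterial list with the highest counts were annotated as mitochondrial porins, which plants also have. Of the 3 algal or protist members 1 fell, flagellar radial spoke protein 5, with a log2 fold change of -0.47 ± 0.10, and 0 passed without control replicate 1 or ILA replicate 1 or on the log2(FPKM + 1) scale. All 3 fell when adjusted over the list alone, with a median of -0.42, and were lower at an unadjusted p under 0.05 in edgeR, DESeq2 and limma. The other 2 were annotated as flagellar dynein light chains. The best NR hits of the 3 were in flowering plants, a duckweed for 2 and Citrus for 1.

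The authors' deposited table lists 408 genes, 306 higher and 102 lower with ILA. In the edgeR test 390 of them were tested and 387 passed the threshold in the same direction. The same 408 genes came from DESeq2 on the rounded counts with adjustment over all 66337 genes with a p-value and a change of over 2-fold. The 3 largest named rises in the authors' deposited table were epidermis-specific secreted glycoprotein EP1 (log2 fold change 5.73), enolase 1 (5.48) and inorganic pyrophosphatase 1 (4.71), and the 3 largest named falls were an alpha carbonic anhydrase 1 (-5.11), serine/threonine-protein kinase CBK1 (-3.85) and high affinity sulfate transporter 2 (-2.87). Some rest on few counts. EP1 had 1 count in all controls and 60 with ILA, a ratio of 62.9 (95% Clopper-Pearson interval 10.9 to 2530, for counting error only), and enolase 1 had 1 and 47, a ratio of 49.3 (8.42 to 1990). This carbonic anhydrase ID (Cluster-6031.0) had 69 counts in controls and 2 with ILA, a 32.9-fold lower level (8.77 to 277), and CBK1 had 43 and 3, a 13.7-fold lower level (4.38 to 68.9).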

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

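Alternatives added after the data had been seen are the sums per Swiss-Prot hit, the Swiss-Prot subset, the lists as first written, DESeq2 without independent filtering, camera on log2(FPKM + 1), and the FPKM alternatives for the 2-fold count and the authors' table. The 2145 genes past the threshold became 1212 with limma on log2(FPKM + 1), 1125 with log2(FPKM + 0.1) and 700 with the FPKM filter. These fits applied no TMM scaling, whose factors were 0.9523 to 0.9869 in controls and 0.9947 to 1.066 with ILA. List medians were higher on log2(FPKM + 1) than in the count test, at -0.45 against -0.56 for light harvesting and 0.08 against -0.01 for auxin genes. How much of the change in calls came from scaling was not tested. Genes higher with ILA went from 1020 to 436 with the FPKM filter. Genes lower with ILA went from 1125 to 428, 390 and 264 in those 3 fits. The 510 genes changed at least 2-fold became 260 with the FPKM filter and 127 with counts summed per Swiss-Prot hit, a fit that tests 9718 sums in place of 31497 IDs. With each library left out in turn, a fit with fewer samples, the count ranged from 1039 (without control replicate 1) to 2121 (without ILA replicate 3), the higher genes from 543 to 952, the lower genes from 496 to 1249, and the 2-fold genes from 326 to 564. Of the lists, 9 were called by camera, 0 with an estimated correlation and 5 by fry, and 9 or 10 with a library left out. Fry asks whether a list moves one way and does not compare it with other genes. Of the 408 genes of the authors' table, 387 passed in the same direction, and 187 with the FPKM filter. The heat shock list was also not called with the filter of 1 CPM (adjusted p = 0.0521), on log2(FPKM + 1) (0.0801), on log2(FPKM + 0.1) (0.082) or summed per Swiss-Prot hit (0.371). The replicate block gave 11 lists, adding the phenylpropanoid and organelle-encoded lists (adjusted p = 0.0169 and 0.0148), with 5 falls among fatty acid genes against 18. It moved other list counts too. Falls went from 28 to 18 for chlorophyll, 8 to 3 for the cell cycle and 9 to 5 for starch. Rises went from 8 to 4 for jasmonate, 11 to 7 for vacuolar and 16 to 10 for glycerolipid genes. Detoxification genes went from 22 up and 13 down to 14 and 7. The other alternatives kept the totals of genes and of lists called, though not every count within a list, within 1.5 times. The genes past the threshold ranged from 1574 with counts summed per Swiss-Prot hit (1576 with the replicate block) to 2880 without a low-count filter. Of 129 named genes past the threshold, 129 stayed past it with DESeq2, 105 with log2(FPKM + 1), 102 with log2(FPKM + 0.1), 70 with the FPKM filter, 111 without control replicate 1 and 115 without ILA replicate 1, and none reversed. The labels do not say whether the replicate numbers pair the samples. Libraries with the same number had correlations of 0.137, -0.175 and -0.297 between their deviations from the group means. Such deviations cancel within each group, so these correlations cannot exclude pairing, and the block is a check of the number alone. Not every library correlated best with its own number. At this depth and number of libraries the simulated tests called 18.2% of genes changed 1.5-fold, and depth alone was not varied.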

Other observations

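The tests here were chosen after the results they measure had been seen, with exceptions for light harvesting genes. Those of expression-matched lists and senescence were added after the fixed lists had been tested but before their own values had been seen. The light harvesting median itself was already known. Fisher's exact test was run on 380 annotated biological processes, against 10466 tested genes with such an annotation. Among rises, the term response to oxidative stress was over-represented, with 19 of 75 members against 3.18 expected (adjusted p = 3.47e-08). With IDs summed per Swiss-Prot hit it had 10 of 39 against 3.33 (adjusted p = 0.0343). A peroxidase reaction term had 19 of 74 with the same adjusted p, so the result may be one of peroxidase genes. The fixed antioxidant and glutathione list was balanced, with 23 up and 24 down of 213. Protein phosphorylation had 53 of 741 against 31.44 (adjusted p = 0.00694, summed 6.26e-08). The starch and the sucrose metabolism terms had the same counts, 20 of 165 against 7.0 expected (adjusted p = 0.00205, summed 0.00215). The fixed starch and sucrose list went both ways, with 6 up and 9 down of 92 (camera adjusted p = 0.899). Cell wall modification had 8 of 33 against 1.4 (adjusted p = 0.00407, summed 0.0343). Among falls, photosynthesis had 36 of 148 against 7.51 expected (adjusted p = 5.07e-13, summed 5.21e-10) and translation 45 of 386 against 19.58 (adjusted p = 2.47e-05, summed 3.5e-05). Steroid biosynthesis, with 14 of 87 against 4.41, was no longer over-represented once IDs were summed (adjusted p = 0.66). Genes are not independent replicates, so these p-values describe the lists of calls.

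The fall of light harvesting genes was set against 3 explanations. Abundance and library scaling do not account for it, since 10000 random lists matched on expression had medians mostly from -0.1 to 0.02, against -0.56. That median came from the fixed lists already tested, so its percentile of 0.0 is no further evidence of a fall. Random lists do not allow for correlation between members, estimated at 0.35. With an estimated correlation camera did not call the list (adjusted p = 0.383), while fry did (adjusted p = 0.0317). A different harvest time in the light-dark cycle may contribute and stays open. The threshold was passed by 18.2% of 22 genes matched as clock genes, the share in the median random list. The 4 that passed (TCP7, LNK1, MYBC1 and APRR2, named after their values were seen) went both ways, and MYBC1 was near the floor (0.864 against 0.149 CPM). The list's median absolute log2 fold change was 0.16. Both LHY IDs (-0.16 and -0.15), GIGANTEA (-0.05), LNK2 (-0.02), APRR5 (0.29) and ELF3 (0.31) did not pass. Another TCP7 ID was at 0.12, and a member named thaumatin-like protein matched through its NR text. Senescence stays open too, since its list had a median of 0.03 with 2 members up and 1 down (camera adjusted p = 0.871). The 3 algal or protist list members were lower too (median -0.42), but their best NR hits were in flowering plants, as were those of the 70 light harvesting genes that fell (a duckweed for 53), and the labels give no harvest hour.

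The rise in the phosphate and sulfate supply list stayed after counts of IDs with the same Swiss-Prot hit were summed. Reads divided among such IDs therefore do not by themselves account for it. After summing per Swiss-Prot hit 17 of 56 members (30.4%) rose, at percentile 100 of random lists of sums matched on expression, whose median share was 7.1%; before summing it was 22.6% against 4.8%. This comparison replaced a first criterion after its value had been seen, and random lists do not allow for correlation between members. A general shortage of nutrients cannot be told apart. The nitrogen list had a median of -0.01 with 4 members up and 7 down, which met the criterion written for rejecting this explanation. The explanation was still left open, because the median is near 0 over members that go both ways. A response to low phosphate is a candidate explanation, but a list of phosphate-saving lipid exchange genes, 6 of 20 up and 0 down with a median at percentile 99.59 of matched random lists, cannot decide it, because all measured members had been seen when it was drawn up, and it was not called with an estimated correlation (adjusted p = 0.326); with the FPKM filter 2 of 22 rose. Phosphate in the medium was not analysed here.

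Some genes of fermentation were higher with ILA, pyruvate decarboxylase 2 (Cluster-4469.27013) from 948 ± 157 to 2180 ± 349 CPM and an alcohol dehydrogenase 2 (Cluster-4469.26285) from 2900 ± 634 to 6020 ± 1340 CPM (SD, n = 3). These were chosen after their values had been seen, another alcohol dehydrogenase (Cluster-4469.35731) was at 0.05 (adjusted p = 0.968), and several IDs carry the dehydrogenase annotation, so the level of each is uncertain. A response to low oxygen may account for this, but the test is weak. Of the 13 measured members of a low oxygen list whose values had not been seen when it was drawn up, 6 rose and 0 fell. Their median of 0.52 lay at percentile 100 of matched random lists, but 3 of 14 rose without control replicate 1 or ILA replicate 1. On the log2(FPKM + 1) scale 4 rose (2 with the FPKM filter). The test was narrowed to these members after the whole list's result had been seen, and they include alcohol dehydrogenase IDs. Their library medians, as log2 deviations from each gene's mean, were -0.33 to -0.05 in controls and 0.03 to 0.33 with ILA. Random lists do not allow for correlation between members, estimated at 0.469 for the whole list. The whole list, 17 of 27 up, was not called with an estimated correlation (adjusted p = 0.258). What might lower oxygen was not tested.

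Whether plastid ribosomal proteins fell rather than ribosomal proteins in general could not be decided. Plastid ribosomal proteins had a median of -0.58 (33 of 49 fell), cytosolic ones -0.34 (17 of 153 fell), both at percentile 0.0 of matched random lists, and mitochondrial ones -0.12 (1 of 23 fell, percentile 8.22); plastid and cytosolic medians differed by -0.24 (permutation p = 1e-05 over genes, the smallest that the permutations can give). The shares of members past the threshold lay on opposite sides of those in matched random lists. For plastid members the share was 67.3% (percentile 100), and for cytosolic members 11.1% (percentile 0.27). The cytosolic share rests on a count of falls that moved with the setting, as given below. Neither the permutation nor the random lists allow for correlation between members. Neither list was called by camera with an estimated correlation (adjusted p = 0.258 for plastid and 0.326 for cytosolic). Library medians, as log2 deviations from each gene's mean, were 0.21 to 0.35 in controls and -0.42 to -0.13 with ILA for the plastid list, and overlapped for the cytosolic list (-0.02 in control replicate 3 and 0.0 in ILA replicate 3). The plastid falls numbered 30 to 34 with a library left out, and the cytosolic falls 1 (without ILA replicate 1) to 71 (without control replicate 3), with 75 by DESeq2's test, 84 without a low-count filter and 1 on the log2(FPKM + 1) scale (0 with the FPKM filter).

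The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2145 genes, 510 of them at least 2-fold, and the highest other split called 1 and 1.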
